A study of Danio rerio with 40 samples.

How the data were processed

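Poly(A) RNA from adult zebrafish eyes and brains was sequenced in 40 samples, 5 for each combination of organ (brain, eye), genotype (WT, wh5) and sex, per the labels. Organ, genotype and sex were taken from the sample titles, because the title and the source field name different organs in all 40 samples. The labels do not say whether brain and eye samples came from the same fish.

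The submitters' processing notes name fastp, STAR, DESeq2 1.32.0 and the genome build GRCz11, with no parameters. The model formula, the filters, and whether sex was a covariate are not given in the sources used here. The deposited files are the authors' own comparisons, 1 table per organ, with NCBI Gene identifiers. Per the file headers, the authors deposited for each gene a log2 fold change and its standard error, also in log2 units. The base of the logarithm is not written in the files and is taken to be 2, as in the output of the tool the authors named. The deposited base mean is a signal, the mean of normalised counts over the samples of the authors' comparison. The deposited test statistic is a score equal to the log2 fold change divided by its SE. The authors also deposited a p-value and an adjusted p-value. The deposited adjusted p was checked to equal the Benjamini-Hochberg value over the listed genes to within a relative difference of 0.00453 in brain and 0.00451 in eye. No table has values of single samples. Depth per library is therefore unknown, and the precision of each value is given by the authors' SE only. For the same reason no count model was fitted here, sexes and replicates were not examined, and no sample was left out.

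A gene was called where the deposited adjusted p was below 0.05. The design fixed before the data were examined allowed for this kind of table and asked for the deposited calls with no refit. The effect of genotype was compared between organs per gene by the difference of the log2 fold changes over the root of the summed squared SEs, with a two-sided normal p and Benjamini-Hochberg adjustment over the 18275 genes in both tables. Overlap of called genes was set beside the number that independent lists would share. Gene lists were tested with cameraPR in limma 3.58.1 (R 4.3.3) on the deposited test statistic, with a preset correlation of 0.01 between genes and adjustment over the lists of both organs together. An estimated correlation needs values of single samples, so no list was tested with one. Lists were compared between organs by the same test on the statistic of the difference, adjusted over the 42 lists. In place of an estimated correlation all lists were also tested with a preset correlation of 0.05. Each called list had a median and a mean of the same sign as its test. Other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

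The 42 lists were written before the data were examined and cover photoreceptors and other retinal cells, lens, cornea, pigment cells, glia, neurons, blood, muscle, liver, immunity, metabolism, hormones, stress and Cyp1 and Ahr genes. They are named with their results. Members were matched by current symbol, by older symbol (17 members) or by symbol pattern, and 46 members were not matched. The counts adjusted over the list alone use a Benjamini-Hochberg adjustment of the deposited p over the measured members.

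Genes named in the text follow a rule fixed before the data were examined. It names cyp1b1 and the Cyp1 and Ahr list. It then takes, per organ, the 12 largest increases and 12 largest decreases among called genes with a base mean of at least 50 and a symbol that is not a clone name. It adds up to 4 called members of each list, or the most expressed members where none was called, the 10 largest changes among genes called in both organs, 5 called genes near cyp1b1 per organ, and marker genes of each organ. The genes noa1, ftr97 and sec63 among those called in both organs were named after their values were seen, except where the rule for 1 organ includes them. Some genes that the rule includes are not reported here.

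Neighbourhood of cyp1b1 was taken from the RefSeq gene table of assembly GRCz12tu, which differs from the build of the authors, so no coordinate is given and the table served only for names and for which genes lie near each other. The design had asked for an annotation of the authors' own build. A place in GRCz12tu was found for 96.1% of genes in brain and 96.4% in eye. Called genes within 10 Mb of cyp1b1 were compared with all other placed genes by Fisher's exact test. The comparison with genes of other chromosomes was added after the data were seen. Intervals of odds ratios are exact conditional 95% intervals.

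The gene tests were tested on simulated data with the deposited SEs, in 20 runs with 200 changed genes each. In brain 79.8% of changes of 1 log2 unit and 55.2% of changes of 0.5 were recovered over 19300 genes, with 5.03% false calls. In eye 78.6% and 49.9% were recovered over 19429 genes, with 4.92% false calls. For the organ difference, 69.1% of differences of 1 log2 unit were recovered over 18275 genes with 5.08% false calls. These runs took the deposited SEs as right, so their share of false calls follows from the threshold. They cannot show whether the SEs are too small, and the deposited eye statistics had a robust SD of 1.317, wider than simulated here. A simulated list shifted by 1 SE was recovered in 100% of cases in brain and 98.3% in eye. Genes were drawn as independent there, so the effect of correlation between genes was not tested. In 200 runs of simulated calls, the interval of the odds ratio held a true ratio of 1 in 98.5% of runs in brain and 95.5% in eye.

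Alternatives were an adjusted p below 0.01, an absolute log2 fold change of at least 1, a base mean of at least 10 with adjustment anew, adjustment anew over all genes, fold changes recentred on the median gene, an empirical null from the median and MAD of the test statistic, and leaving out the chromosome of cyp1b1. For lists they were a preset correlation of 0.05, ranks, the log2 fold change as the value and a base mean of at least 10. Chosen after the data were seen were the empirical null for genes called in both organs, the alternatives for the list differences between organs, and lists without the genes of the cyp1b1 chromosome and without the ribosomal protein S6 kinase genes.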

Results

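RNA was sequenced from whole eyes and brains of adult zebrafish of the wh5 line, which carries a knockout of cyp1b1, and of wild-type (WT) fish. Cyp1b1 is a cytochrome P450 enzyme that oxidises steroids, retinoids and fatty acids. The 40 samples form 8 groups of 5, defined by organ, genotype and sex, so that each organ has 10 WT and 10 wh5 samples. The data used here are the authors' deposited tables, 1 per organ, which compare wh5 with WT and hold no value of a single sample. The depth of each library is therefore unknown, sexes could not be compared, and each value below carries the standard error (SE) of the authors' model. The brain table lists 19300 genes with a median SE of 0.13 on the log2 scale, and the eye table lists 19429 genes with a median SE of 0.14. A gene at the median SE has a 95% interval of 0.25 log2 units to either side in brain and 0.28 in eye. In all 40 samples the title names one organ and the source field names the other, and organs were taken from the titles. Base means (means of normalised counts over both genotypes) in the authors' deposited tables follow the organ each table is named for. Rhodopsin (rho) had a base mean of 632710 in the eye table and 1359 in the brain table, and the neuronal gene elavl3 had 3012 and 11919, respectively.

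The first question was whether the targeted transcript itself differed. In the authors' deposited table for brain, cyp1b1 had a log2 fold change of -0.17 (SE 0.14, adjusted p = 0.818) at a base mean of 669. In the eye it was higher in wh5, by 0.54 on the log2 scale (SE 0.14, adjusted p = 0.016) at a base mean of 453.5, again from the authors' deposited table, a call lost with an empirical null (adjusted p = 0.464). A lower transcript level in wh5 was called in neither organ, although the 95% interval of the fold in brain, 0.733 to 1.08, allows one, and the level does not check the genotype labels or the direction of the comparison. Directions are read as wh5 over WT from the names of the tables.

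In the brain, genes of the cone photoreceptor cascade were lower in wh5. By the authors' deposited table, the blue cone opsin gene opn1sw2 fell, with a log2 fold change of -3.85 (SE 1.03, adjusted p = 0.0301), and the cone opsin kinase gene grk7a by -3.73 (SE 0.94, adjusted p = 0.0154). The cone transducin gene gnat2 changed by -3.05 (SE 0.86), the cone arrestin gene arr3b by -3.01 (SE 0.75) and the guanylate cyclase activator gene guca1d by -3.12 (SE 0.79) in the authors' deposited table. Of 31 measured cone genes, 5 fell, none rose, and the median log2 fold change was -1.86 (cameraPR in limma, adjusted p = 1.8e-11). None of the 5 calls held when p-values were recomputed from an empirical null (adjusted p from 0.064 for arr3b to 0.171 for gnat2), and opn1sw2 and gnat2 also lost theirs without the chromosome of cyp1b1 (0.0514 and 0.0796). Adjusted over the list alone, 13 cone genes were lower and 1 was higher. Rod genes had a median of -1.51 over 29 measured members (adjusted p = 1.8e-09), none of which was called over all genes, and 2 were lower when adjusted over the list alone. Expression of these genes in brain was low and variable. The 23 rod genes at least 100 times higher in the eye table had in brain a median of 0.31% of their eye base mean. Whether less retina was carried over into the wh5 brain samples stays open, as weighed below. The cone list had a median base mean of 49.6 and a median SE of 0.86 in the authors' deposited table, against a median SE of 0.13 over all genes. The pineal list had a median of -1.196 over 23 measured genes (adjusted p = 3.5e-06). It shares 7 genes with the cone list and 2 with the rod list, and its called members were gnat2 and grk7a, which also belong to cones.

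Immediate early genes were lower in wh5 brain as a list. The immediate early transcription factor genes npas4a, egr1 and egr4 and the antiproliferative gene btg2 were the 4 called members among 49 measured. In the authors' deposited table their log2 fold changes were -0.77 (SE 0.13, adjusted p = 1.8e-06) for npas4a and -0.57 (SE 0.10, adjusted p = 6.66e-06) for egr1. For egr4 the authors' deposited table gives -0.80 (SE 0.15) and for btg2 -0.57 (SE 0.13). The list's median was -0.10 (adjusted p = 9.35e-07), and 5 members were lower when adjusted over the list alone. With the log2 fold change in place of the test statistic the adjusted p of this list was 0.063.

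Several other lists also passed in brain, with medians from -0.11 to 0.36. The 101 nuclear oxidative phosphorylation genes had a median log2 fold change of -0.11 (adjusted p = 2.2e-06) and no called member. The 92 genes of the ribosomal protein list had a median of -0.11 (adjusted p = 1.5e-05). Its called member, rps6ka2, encodes a signalling kinase and not a ribosomal protein, and is 1 of 11 ribosomal protein S6 kinase genes that the symbol pattern took in. The authors' deposited table gives rps6ka2 a log2 fold change of 0.70 (SE 0.12). Heat shock and chaperone genes had a median of -0.09 over 36 members (adjusted p = 0.00013). With the log2 fold change as the value the adjusted p was 0.11 for oxidative phosphorylation, 0.33 for ribosomal proteins and 0.12 for chaperones. Retinoid genes had a median of -0.07 over 57 members (adjusted p = 0.017). The called retinoid member was rgra, an opsin-like photoisomerase gene that lies on the chromosome of cyp1b1. The retinoid list also includes rbp3, which is in the pineal list, and its lowest log2 fold change was -2.87. It was not tested without such genes, so its shift is not separate from that of the photoreceptor genes. Cornea and surface epithelium markers, at a median base mean of 27.3, had a median of 0.36 over 29 members (adjusted p = 0.0021), none called. With a preset correlation of 0.05 between genes the retinoid and cornea lists no longer passed (adjusted p = 0.25 and 0.057).

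Among single genes in brain, the largest rises among called genes with a base mean of at least 50 and no clone name were in vox, pyroxd2 and fndc1. The authors' deposited table gives log2 fold changes of 1.92 (SE 0.29) for vox, a ventral homeobox gene, and 1.12 (SE 0.15) for pyroxd2, an oxidoreductase gene. The replication helicase gene mcm7 rose by 1.06 (SE 0.24) and the dynamin gene dnm1a by 1.04 (SE 0.27) in the authors' deposited table. Decreases outside the photoreceptor genes included the lysyl oxidase-like gene loxl3b at -2.15 (SE 0.35) and the thrombospondin gene thbs2a at -1.22 (SE 0.21), as the authors' deposited table gives them. The steroid 5-alpha-reductase gene srd5a2b fell to a log2 fold change of -1.52 (SE 0.29, base mean 33.6) and the cytochrome P450 gene cyp2p10 by -0.77 (SE 0.19) in the authors' deposited table. In all, 142 of 19300 genes had an adjusted p below 0.05 in the authors' deposited table, 71 higher and 71 lower in wh5. Of these, 57 lie on the chromosome that holds cyp1b1, among them vox, pyroxd2, loxl3b, thbs2a and srd5a2b, and 65 genes passed when that chromosome was left out. When p-values were recomputed from an empirical null, 77 genes passed, without fndc1, dnm1a and cyp2p10 (adjusted p = 0.143, 0.0713 and 0.0555).

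**Figure D1:**
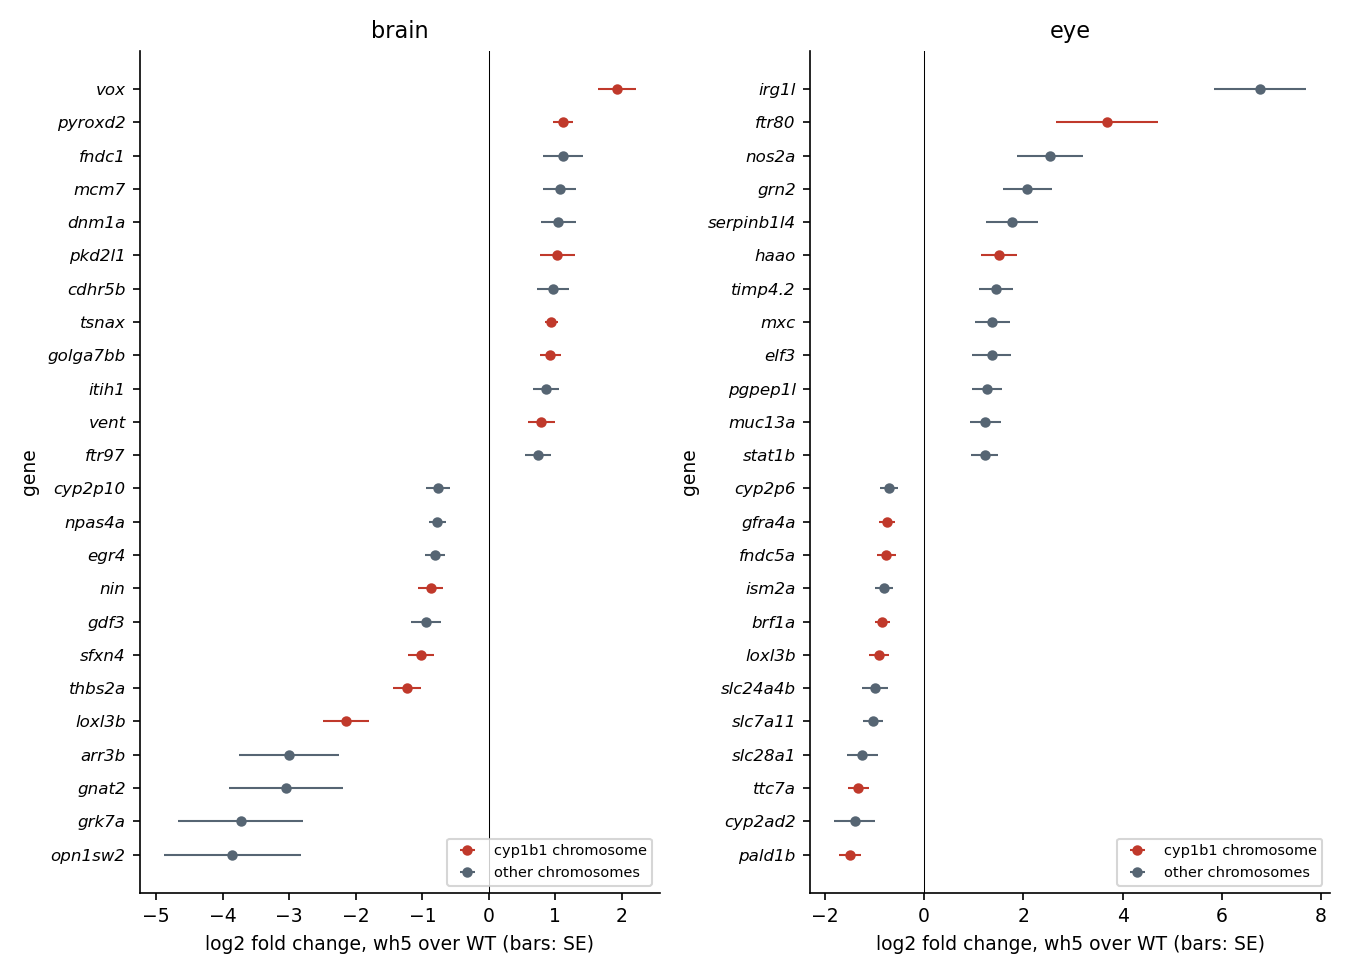
Log2 fold change (wh5 over WT, x axis) of the 12 most increased and 12 most decreased called genes (y axis) with a base mean of at least 50 and a symbol that is not a clone name, in brain (left) and eye (right), from the authors' deposited tables. Points are the authors' estimates, bars are 1 SE, and red marks genes on the chromosome that holds cyp1b1. In brain the cone genes opn1sw2, grk7a, gnat2 and arr3b are the lowest of those plotted, and in eye irg1l is the highest of those plotted at 6.77.

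In the eye, interferon response genes and some other immune genes were higher in wh5. The complement and acute phase list did not pass (median -0.02 over 28 members, cameraPR adjusted p = 0.98, none called). Among called genes with a base mean of at least 50 and no clone name, the largest rise was in irg1l, related to the gene of the itaconate-producing enzyme of macrophages, with a log2 fold change of 6.77 (SE 0.93, adjusted p = 1.35e-09) in the authors' deposited table. The inducible nitric oxide synthase gene nos2a rose by 2.54 (SE 0.67), the granulin gene grn2 by 2.08 (SE 0.50) and the finTRIM gene ftr80 by 3.69 (SE 1.03), all from the authors' deposited table. Of the immune genes named for eye, ftr80 and ifit8 lie on the chromosome that holds cyp1b1. Of 51 measured interferon response and antigen presentation genes, 4 rose, none fell, and 16 were higher when adjusted over the list alone. The called members in the authors' deposited table were ifit8 at 2.45 (SE 0.70), mxc at 1.37 (SE 0.35), stat1b at 1.22 (SE 0.27) and b2m at 0.50 (SE 0.13). The list's median was 0.50 (adjusted p = 1.1e-12). With an empirical null none of these 4 genes was called (adjusted p from 0.192 for stat1b to 0.623 for ifit8), nor were nos2a (0.443), grn2 (0.342) and ftr80 (0.583), while irg1l was (0.000183). Microglia and leukocyte markers moved the same way with a median of 0.21 over 41 members (adjusted p = 0.0058). The macrophage gene mpeg1.2 was their called member, at 1.203 (SE 0.33, adjusted p = 0.525 with an empirical null) in the authors' deposited table, and 7 were higher and 1 lower when adjusted over the list alone. With a preset correlation of 0.05 the leukocyte list no longer passed (adjusted p = 0.13). Cornea and surface epithelium markers had a median of 0.30 over 32 members (adjusted p = 0.0019, and 0.057 with a preset correlation of 0.05). The epithelial calcium-binding gene icn2 was called in that list, at 0.79 (SE 0.21) in the authors' deposited table. Tandem copies and multigene families, such as mpeg1.2, the finTRIM genes and the green cone opsins, can share reads, and how the authors counted such reads is not given in the sources used here.

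Lists of ribosomal protein, nuclear oxidative phosphorylation and cell cycle genes were higher in wh5 eye. Ribosomal protein genes had a median log2 fold change of 0.22 over 92 members (adjusted p = 8.2e-12) and oxidative phosphorylation genes 0.16 over 101 members (adjusted p = 6.7e-06), with no called member in either. With the log2 fold change as the value the oxidative phosphorylation list had an adjusted p of 0.063. Mitochondrially encoded genes and tricarboxylic acid cycle genes did not pass in eye (medians -0.01 and 0.03, cameraPR adjusted p = 0.97 for each). Cell cycle genes had a median of 0.19 over 91 members (adjusted p = 4.5e-06). Their called members in the authors' deposited table were mcm7 at 0.93 (SE 0.18) and the survivin gene birc5a at 0.98 (SE 0.29). Rod genes had a median of 0.13 over 29 members (adjusted p = 0.012) and cone genes 0.03 over 36 members (adjusted p = 0.95), with no called member in either list. Glutathione and oxidative stress genes had a median of 0.10 over 81 members (adjusted p = 0.013). In that list gstz1 rose by 0.66 (SE 0.19) and the cystine transporter gene slc7a11 fell to a log2 fold change of -1.02 (SE 0.20) in the authors' deposited table. The rod and glutathione lists did not pass with a preset correlation of 0.05 (adjusted p = 0.13 and 0.27).

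Xenobiotic response genes included called members in eye. In the authors' deposited table ahrra, a repressor of the aryl hydrocarbon receptor, rose by 0.78 (SE 0.14, adjusted p = 2.75e-05) and cyp1a by 0.79 (SE 0.23, adjusted p = 0.0354). With an empirical null ahrra was still called (adjusted p = 0.0256) and cyp1a was not (0.623). With cyp1b1 itself they were the 3 called members of the 14 measured Cyp1 and Ahr genes, whose median was 0.06 (adjusted p = 0.046). By ranks the list had an adjusted p of 0.40, without the chromosome of cyp1b1 0.16, and with a preset correlation of 0.05 0.17. In brain the 13 measured members had a median of 0.07 (adjusted p = 0.68), none called.

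Some of the neural lists were lower in wh5 eye. Neuron and synapse genes had a median of -0.10 over 68 members (adjusted p = 0.00024), with the neurofilament gene nefma at -0.69 (SE 0.20) and the synaptotagmin gene syt2a at -0.47 (SE 0.13) called in the authors' deposited table. Retinal interneuron and ganglion cell markers had a median of -0.09 over 27 members (adjusted p = 0.019). GABA, glycine and glutamate transmission genes had a median of -0.07 over 85 members (adjusted p = 0.034), with the NMDA receptor gene grin2da called at -0.56 (SE 0.16) in the authors' deposited table. The neuropeptide list and the dopamine, serotonin and acetylcholine list did not pass (adjusted p = 0.37 for each). Myelin genes had a median of -0.20 over 19 members (adjusted p = 0.028), cholesterol synthesis genes -0.09 over 32 (adjusted p = 0.038) and extracellular matrix genes -0.08 over 55 (adjusted p = 0.041), with no called member. Heat shock and chaperone genes had a median of -0.13 over 37 members (adjusted p = 0.00046), with the small heat shock gene hspb8 called at -0.35 (SE 0.08) in the authors' deposited table. With a preset correlation of 0.05 the chaperone list still passed (adjusted p = 0.039), while the neuron and synapse list did not (0.057), nor did the other lists of this group (0.16 to 0.40). The glutamine synthetase gene glula of Muller glia was called at -0.26 (SE 0.07) in the authors' deposited table. Its list of Muller glia and astroglia markers did not pass, with 13 members higher and 12 lower (median 0.01, cameraPR adjusted p = 0.97).

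In all, 325 of 19429 genes had an adjusted p below 0.05 in the authors' deposited table for eye, 189 higher and 136 lower in wh5. The other decreases among the 12 largest included the solute carrier gene slc28a1 at -1.25 (SE 0.31), pald1b at -1.49 (SE 0.22) and ttc7a at -1.33 (SE 0.21), as given in the authors' deposited table, of which pald1b and ttc7a lie on the chromosome that holds cyp1b1. The eye test statistics were wider than a standard normal distribution, with a robust SD of 1.317 against 1.104 in brain. When p-values were recomputed from an empirical null, 38 genes passed in eye, without nefma, syt2a, grin2da, hspb8, glula, icn2, birc5a, gstz1, slc28a1 and mcm7 (adjusted p from 0.0526 for mcm7 to 0.660 for gstz1) but with slc7a11, pald1b and ttc7a. With an absolute log2 fold change of at least 1, 95 genes passed, of which 80 were higher and 15 lower.

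**Figure D2:**
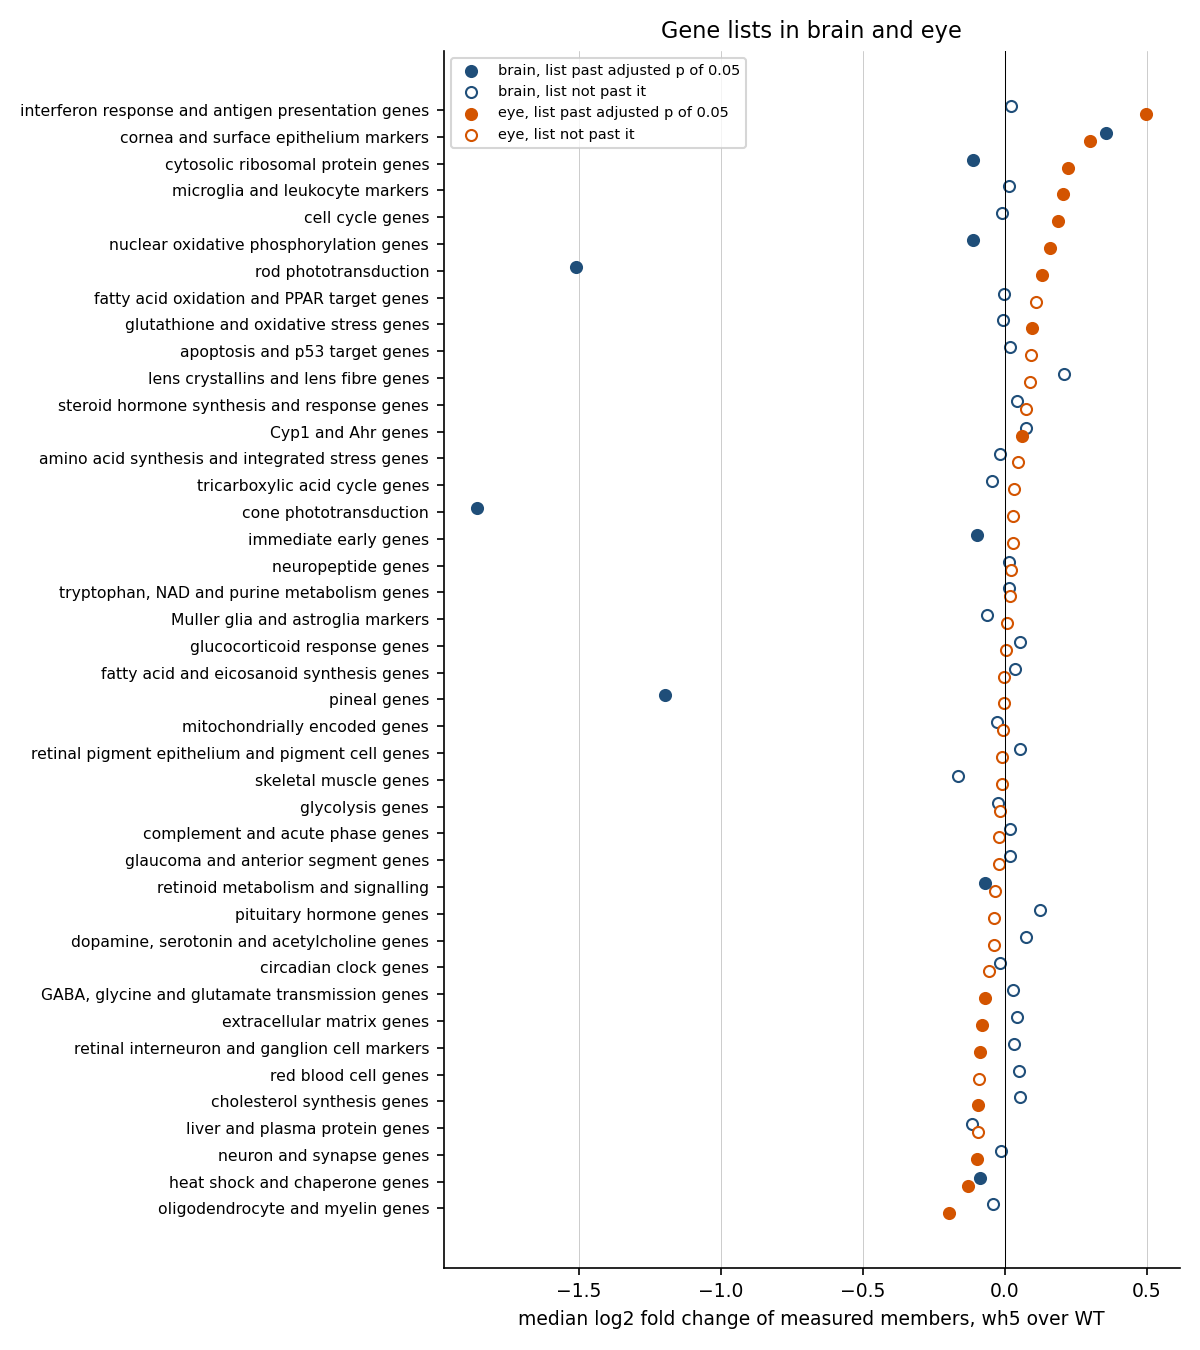
Median log2 fold change (wh5 over WT, x axis) of the measured members of each of the 42 gene lists (y axis) in brain (blue) and eye (orange), computed from the authors' deposited tables. Filled points mark lists with an adjusted p below 0.05 by cameraPR. Cone, rod and pineal lists lie at -1.86, -1.51 and -1.196 in brain, and the interferon list lies at 0.50 in eye.

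The line carries its mutant allele on a stretch of chromosome, so the position of called genes was examined. In brain, 31 of 230 tested genes within 10 Mb of cyp1b1 were called, against 107 of 18312 other placed genes, an odds ratio of 26.5 (95% interval 16.7 to 40.9, Fisher's exact test, two-sided p = 2.19e-30). In eye, 25 of 237 genes within 10 Mb were called against 292 of 18483, an odds ratio of 7.34 (4.57 to 11.4, Fisher's exact test, two-sided p = 3.27e-13). These tests count genes as independent, so where neighbours change together the intervals are too narrow and the p-values too small. Over the whole chromosome, 57 of 709 genes (8.04%) were called in brain and 61 of 717 (8.51%) in eye. On the other chromosomes together the shares were 0.454% and 1.42%, and no single one of these 24 chromosomes exceeded 1.35% in brain or 2.45% in eye. Genes of the same chromosome more than 10 Mb from cyp1b1 were also called more often than genes of other chromosomes, with odds ratios of 12.6 (7.68 to 19.99) in brain and 5.62 (3.80 to 8.10) in eye. The called genes of this chromosome went both ways, with 30 higher and 27 lower in brain and 28 higher and 33 lower in eye. Within 10 Mb, the smallest adjusted p in brain belonged to tsnax, the gene of a translin-binding protein, with a log2 fold change of 0.94 (SE 0.10, adjusted p = 2.85e-16) in the authors' deposited table. In eye, si:dkeyp-2e4.3 fell to a log2 fold change of -3.59 (SE 0.42, adjusted p = 1.85e-13), as the authors' deposited table gives it.

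**Figure D3:**
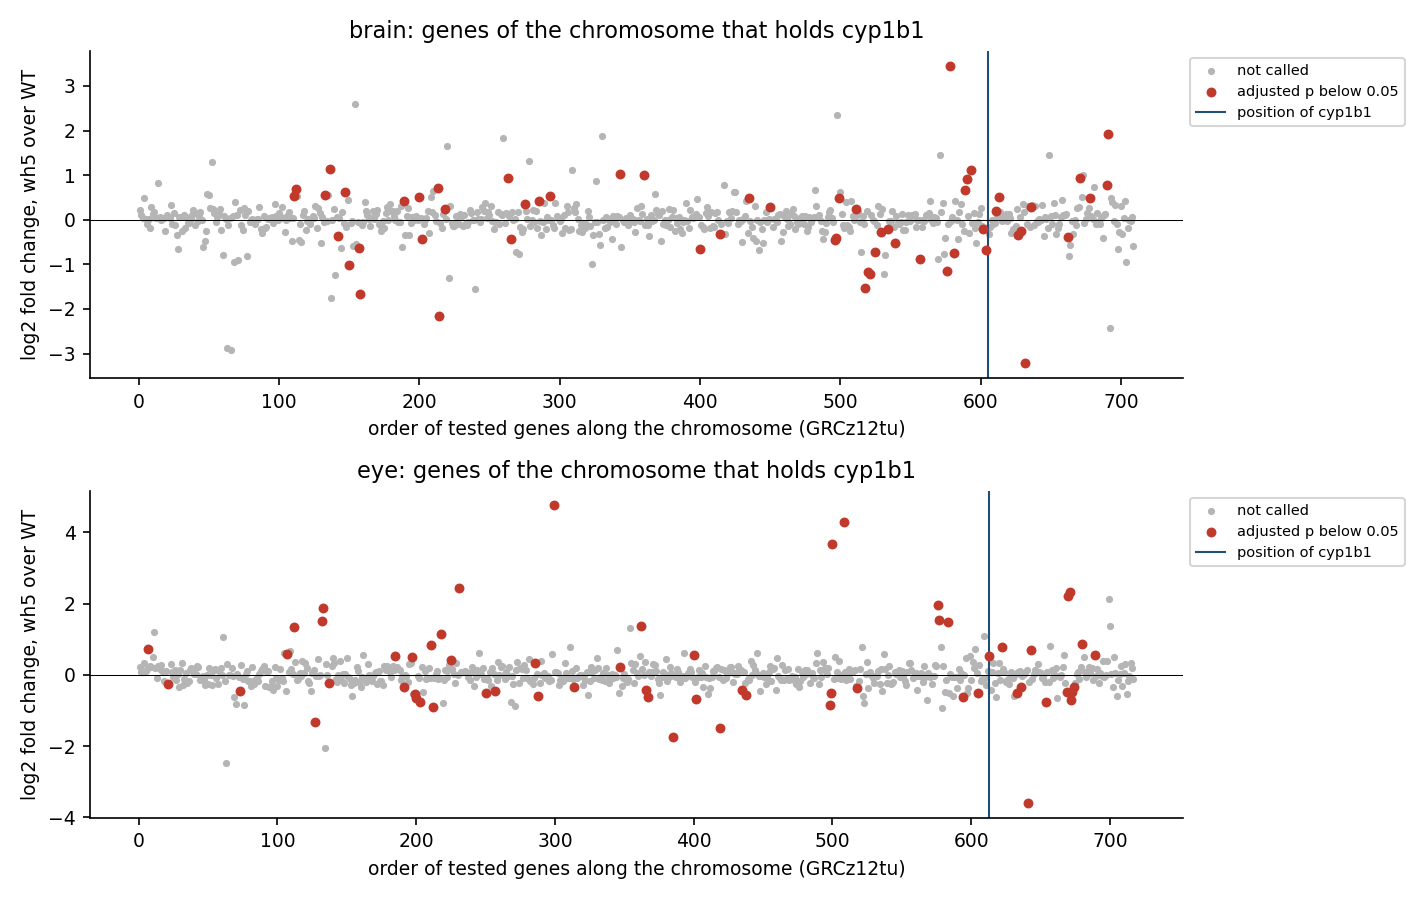
Log2 fold change (wh5 over WT, y axis) of each tested gene of the chromosome that holds cyp1b1, in the order of genes in GRCz12tu (x axis), for brain (top) and eye (bottom), from the authors' deposited tables. Red points are genes with an adjusted p below 0.05, grey points are other genes, and the line marks cyp1b1. The 57 called genes in brain and 61 in eye lie on both sides of the zero line and along most of the chromosome.

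The 2 organs were compared over the 18275 genes tested in both. Of 137 genes called in brain and 286 called in eye among them, 25 were called in both, all in the same direction (15 higher and 10 lower in wh5). Independent lists of these sizes would share 1.07 genes in the same direction. Of the 25 genes, 18 lie on the chromosome that holds cyp1b1, and 7 were shared over the rest of the genome, where independent lists would share 0.533. The shared genes elsewhere were mcm7, dnm1a, the finTRIM gene ftr97, the mitochondrial GTPase gene noa1, the translocon gene sec63, and the uncharacterised si:ch73-106g13.1 and LOC100536937, of which the last has no chromosome. With an empirical null 10 genes were called in both organs, 9 of them on the chromosome of cyp1b1 and the other LOC100536937. By that null mcm7, noa1 and si:ch73-106g13.1 were called in brain alone, and dnm1a (adjusted p = 0.0713 in brain and 0.346 in eye), ftr97 (0.105 and 0.412) and sec63 (0.143 and 0.330) in neither organ. In the authors' deposited tables dnm1a had log2 fold changes of 1.04 (SE 0.27) in brain and 0.83 (SE 0.20) in eye. Log2 fold changes of the 2 organs had a Spearman correlation across genes of 0.37 on the cyp1b1 chromosome and 0.16 on the others, where genes are not independent replicates. Brain and eye samples share no control library, but may come from the same fish.

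**Figure D4:**
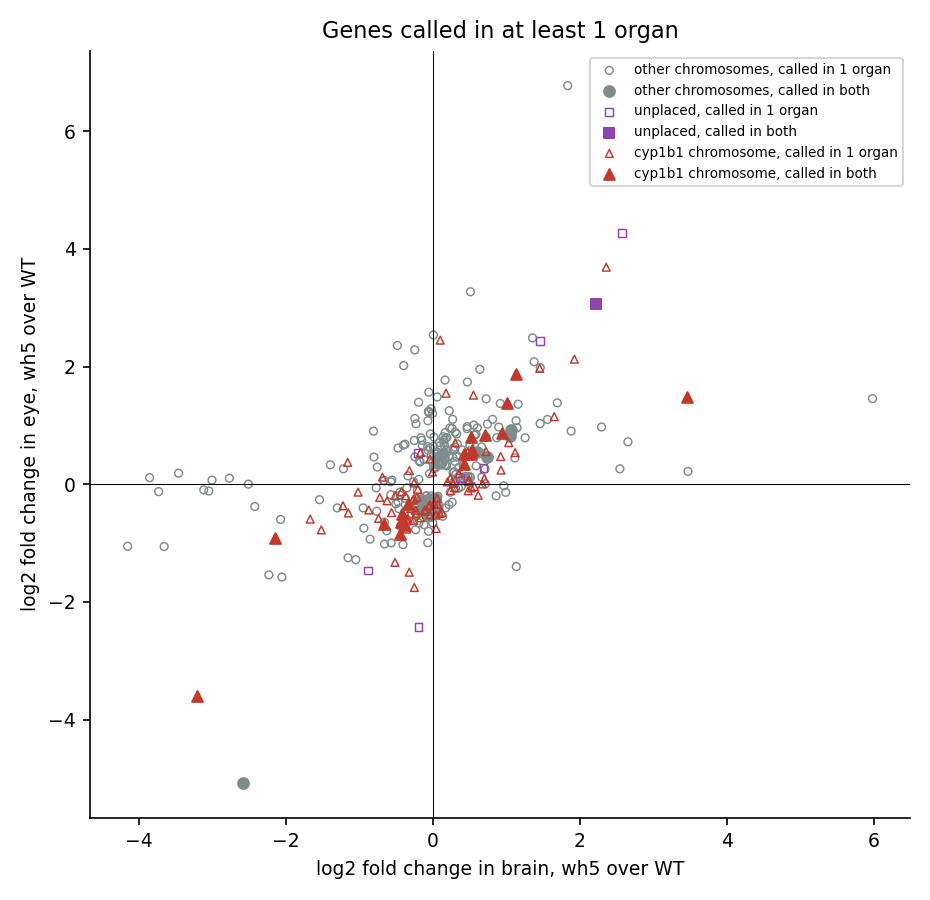
Log2 fold change (wh5 over WT) in brain (x axis) against eye (y axis) for genes called in at least 1 organ and tested in both, from the authors' deposited tables. Filled symbols are the 25 genes called in both organs and triangles are genes on the chromosome that holds cyp1b1. The 25 filled symbols lie in the quadrants of equal sign.

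The genotype effect itself differed between organs for 15 genes by the test of the difference, treating the organs as independent, with 4 genes above and 11 below in brain. With an adjusted p below 0.01 the count was 2. It was 727 (373 above and 354 below) with a correlation of 0.5 set between the organs' estimates, in case samples shared fish. Across all genes the log2 fold changes of the organs correlated less than that (Spearman 0.18, Pearson 0.34). The setting of 0.5 may therefore be too high, which would make 727 too large. Without adjustment, 1496 of 18275 genes had a p below 0.05 in this two-sided normal test on the authors' estimates. A share of 0.05 of the genes would pass that level with no difference at all. No empirical null was applied to this test, although the eye test statistics were wider than a standard normal distribution. Of the genes named here, egr4 was lower in wh5 brain and had a log2 fold change of 0.46 (SE 0.18) in eye, a difference of -1.27 (SE 0.23, adjusted p = 0.0012 from the authors' deposited tables). Of the 42 lists, 15 differed between organs, and 8 with a preset correlation of 0.05, all of them lower in brain. Ribosomal protein and oxidative phosphorylation lists had medians below 0 in wh5 brain and above 0 in wh5 eye (cameraPR adjusted p of the difference 4.6e-23 and 3.7e-15). With a preset correlation of 0.05 these were 7.0e-08 and 2.0e-05. The shifts were small. With the log2 fold change as the value, neither list passed in brain (adjusted p = 0.33 and 0.11), nor did oxidative phosphorylation in eye (0.063).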

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

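Tests chosen only after the result was seen are the comparisons of lens levels between the tables and the fold changes of eye-enriched lens, cornea and pigment genes in brain. The higher preset correlation used here for lists that differ between organs was also chosen after the data were seen. The other tests of this part were fixed before their results were seen. Bootstrap intervals in this part, and the upper bound for lens levels, resample the genes of a set and not fish. They leave out variation between animals. These results stand out because the effect of genotype differed between brain and eye by the test of the difference itself, with the organs treated as independent.

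Among named genes, the log2 fold change in brain minus that in eye was -1.27 for egr4, 0.79 for gfra4a, a receptor gene of the GDNF family, and 1.17 for pald1b, all computed from the authors' deposited tables (adjusted p = 0.0012, 0.0254 and 0.0113). In the eye, gfra4a and pald1b had log2 fold changes of -0.75 (SE 0.16) and -1.49 (SE 0.22) in the authors' deposited table. With an empirical null pald1b was called in eye and gfra4a was not (adjusted p = 0.128). Both genes lie on the chromosome that holds cyp1b1.

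Of the 42 lists, 10 lay lower in brain than in eye relative to other genes. The adjusted p of the difference was 4.6e-23 for ribosomal proteins, 3.7e-15 for oxidative phosphorylation, 1.8e-14 for rods, 1.77e-11 for cones, 1.4e-08 for interferon and antigen presentation, 1.4e-06 for pineal genes and 2.2e-05 for the cell cycle. It was 0.000204 for immediate early genes, 0.0043 for glutathione and oxidative stress, and 0.0491 for fatty acid oxidation and PPAR targets. The 5 lists that lay higher in brain than in eye were cholesterol synthesis (adjusted p = 0.0078), GABA, glycine and glutamate transmission (0.0134), neuron and synapse genes (0.0134), dopamine, serotonin and acetylcholine genes (0.0379) and extracellular matrix (0.0491). With a preset correlation of 0.05 none of these 5 passed (0.120 to 0.322), nor did glutathione and oxidative stress (0.190) or fatty acid oxidation (0.328).

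Photoreceptor genes were lower in wh5 brain, and lay lower there than in eye by the test of the difference, which tissue taken with the brain at dissection may account for. Less pineal tissue is argued against by 7 measured pineal genes, among them exorh, aanat2 and asmt2. Their weighted mean log2 fold change, in which asmt2 (SE 0.11) weighs most, was 0.06 with a lower 95% bound of -0.11. That bound treats genes measured in the same brains as independent, so it may be too narrow. Their median was -0.18, and 4 of the 7 were lower. The lowest, aanat2 at -0.53 (SE 0.37), was still far from the median change of the cone genes. Less whole eye, lens included, is argued against by levels: of the 5 lens genes most abundant in eye among those in both tables, 4 had in brain a smaller share of their eye base mean than any of 45 eye-enriched rod and cone genes, and all 5 lay at or below 0.406 of the level that the rod genes' share would give (6.94 against 1173 for crygs1), although a test tried before it, of the 18 of 40 abundant lens genes listed in brain, was undecided (median 0.49, upper bound 1.104). Less retina stays open. In brain, 243 genes at least 100 times higher in the eye table, without the cone list, had a median of -0.40 (95% bootstrap interval -0.61 to -0.18). The median did not reach the fall set in advance for less eye tissue, and the lower bound was not above the level set against it. This set holds genes of all eye tissues, 15 of the lens list and 13 of the cornea list among them, so it cannot test retina alone. Of rod and cone genes so enriched in eye, 23 of 23 and 21 of 22 were lower (medians -1.61 and -2.61), but these are the pattern to be explained. Fold changes of eye-enriched lens, cornea and pigment genes (medians 0.38, 0.71 and -0.02) are measured too near the floor to exclude less retina. A change in photoreceptor-like cells of the brain was not tested.

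Interferon response and antigen presentation genes were higher in wh5 eye. More leukocytes may contribute, and the test cannot settle it. The 39 leukocyte markers outside the interferon list had a median of 0.17 (95% bootstrap interval over genes 0.04 to 0.42). This overlaps 0.25, the level set in advance as 50% of the interferon median. A few strongly responding eyes are a candidate explanation, for which larger SEs had been set in advance as the prediction. The SE of the interferon genes was 1.60 times that of genes of like base mean (95% bootstrap interval over genes 1.36 to 1.78). Other sources of spread between fish, such as sex, would widen it too, so the ratio cannot single out a few eyes. A response to the loss of Cyp1b1 itself stays open as untested.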

How the results depend on the processing

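Tests chosen after the data were seen are the lists without the cyp1b1 chromosome, the list without kinase genes, the comparison with other chromosomes, the empirical null for genes called in both organs and the alternatives for lists that differ between organs. No result given here changed direction past its threshold under the alternatives run for it. Called genes in brain numbered 142, and 75 with an adjusted p below 0.01, 45 with an absolute log2 fold change of at least 1, 77 with an empirical null and 65 without the chromosome of cyp1b1, in each case among the 142. In eye 325 genes were called, and 122, 95 and 38 under the same first 3 alternatives, all among the 325, with 234 left without the chromosome. A base mean of at least 10, recentring and adjustment anew gave 140 to 149 genes in brain and 321 to 342 in eye. Adjustment anew changed no call, since the deposited values are already adjusted over the listed genes. The stricter thresholds and the wider null admit fewer genes by construction. Genes called in both organs numbered 25, and 16 with an adjusted p below 0.01, 6 with an absolute log2 fold change of at least 1, 7 without the chromosome of cyp1b1 and 10 with an empirical null. Genes that differed between organs numbered 15, 2 with an adjusted p below 0.01, and 727 if the organs' estimates were correlated at 0.5, which narrows the SE of the difference. Across all genes the fold changes of the organs correlated less than that (Spearman 0.18, Pearson 0.34), so 727 may be too large. The odds ratio near cyp1b1 stayed above 1 in every window and threshold, from 19.1 to 75.8 in brain and 6.44 to 19.6 in eye. In brain 9 lists passed and 7 to 11 under the alternatives, where 5 of the 8 that passed with the log2 fold change were among the 9. In eye 16 lists passed, but 5 with a preset correlation of 0.05, which widens the test, and 7 with the log2 fold change as the value, where the cause was not tested. Over both organs, 25 of 84 list results were called. Of these 25, 13 lost their call with the preset correlation of 0.05, 13 with the log2 fold change, 1 with ranks and 1 without the chromosome of cyp1b1. Among the list results not called, 3 gained a call with the log2 fold change and 3 with ranks. Only part of the 247 values of named genes were called, since the rule also names genes that were not. With an empirical null, 22 called values kept their call and 15 lost it in brain, and 14 kept it and 54 lost it in eye. Over both organs, 69 called values lost their call with an empirical null, 50 with an adjusted p below 0.01, 56 with an absolute log2 fold change of at least 1 and 1 with recentring. Without the chromosome of cyp1b1, 8 lost theirs (opn1sw2, gnat2, fndc1 and cplx2 in brain, birc5a, gstz1, cyp2ad2 and serpinb1l4 in eye), with adjusted p from 0.0509 to 0.0796. Lists that differed between organs numbered 15, but 8 with the preset correlation of 0.05 and 10 with the log2 fold change, of which 8 were among the 15. They numbered 13 to 15 with ranks, organs correlated at 0.5, a base mean of at least 10 (40 lists) and without the chromosome. No paired analysis was possible because the tables hold no values of single samples. For the same reason these alternatives, chosen before the data were examined, were not run: other count models and size factors, a sex term or the sexes apart, a replicate block, leaving out samples, another pseudocount and an estimated correlation. Other splits of the samples were not examined either. Precision is limited by the SEs, and depth per library is unknown.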

Other observations

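Tests chosen after the result was seen are those of genes more than 10 Mb from cyp1b1, of the share of higher and lower genes on its chromosome and of equal signs in both organs. The odds ratio over the whole chromosome was chosen before the data were examined, but its use to weigh an explanation was not. The test of neighbouring genes on other chromosomes was fixed before its result was seen.

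Single genes changed in lists that did not pass as a whole. In eye, genes of circadian timing went both ways in the authors' deposited table, with the clock gene arntl1a at 0.32 (SE 0.09), aanat1 of melatonin synthesis at 0.46 (SE 0.12) and the repressor gene bhlhe41 at -0.20 (SE 0.05). Genes of purine metabolism also went both ways in eye, with hprt1l at -0.53 (SE 0.11), gmps at -0.41 (SE 0.09) and ampd3b at 0.57 (SE 0.17) in the authors' deposited table. The tryptophan catabolism gene haao rose by 1.51 (SE 0.36), the acetylcholine synthesis gene chata by 0.55 (SE 0.10) and the glycolysis gene pfkmb by 0.66 (SE 0.16), again from the authors' deposited table for eye. Of these, haao and chata lie on the chromosome that holds cyp1b1. The steroid synthesis gene cyp17a1, on the same chromosome, fell to a log2 fold change of -1.75 (SE 0.35, base mean 24.1), and cyp3c1 rose by 0.55 (SE 0.14) in the authors' deposited table for eye. In the Cyp2 family, cyp2ad2 fell at -1.40 (SE 0.42) and cyp2p6 at -0.71 (SE 0.18) in the authors' deposited table for eye. With an empirical null only chata of the genes named here was still called (adjusted p = 0.0233), and the others lay between 0.0533 and 0.635.

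Other lists passed in neither organ by the deposited test statistic, although in brain lens, skeletal muscle and Muller glia passed with the log2 fold change as the value (adjusted p = 0.0139, 0.0245 and 0.0139). By ranks, lens (0.0451) and dopamine, serotonin and acetylcholine genes (0.0394) passed in brain and fatty acid oxidation genes (0.0272) in eye. In brain and eye, respectively, the median log2 fold change was 0.21 and 0.09 for lens, 0.05 and -0.01 for pigment cells, -0.16 and -0.01 for skeletal muscle, 0.05 and -0.09 for red blood cells and -0.12 and -0.10 for liver and plasma proteins. It was 0.12 and -0.04 for pituitary hormones, 0.02 and 0.02 for neuropeptides, 0.05 and 0.01 for glucocorticoid response, 0.04 and 0.08 for steroid hormones and 0.07 and -0.04 for dopamine, serotonin and acetylcholine. For metabolism it was -0.02 and -0.02 for glycolysis, -0.04 and 0.03 for the tricarboxylic acid cycle, -0.03 and -0.01 for mitochondrially encoded genes, 0.00 and 0.11 for fatty acid oxidation and 0.04 and 0.00 for fatty acid and eicosanoid synthesis. It was 0.01 and 0.02 for tryptophan, NAD and purine metabolism and -0.02 and 0.05 for amino acid synthesis. It was -0.02 and -0.06 for the circadian clock, 0.02 and 0.09 for apoptosis, 0.02 and -0.02 for complement, 0.02 and -0.02 for glaucoma and anterior segment genes, and -0.06 and 0.01 for Muller glia and astroglia. Over all lists that did not pass by the test statistic, the adjusted p ran from 0.071 to 0.97 in brain and from 0.062 to 0.98 in eye.

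Called genes were concentrated on the chromosome that holds cyp1b1. An effect of lost Cyp1b1 activity alone, on genes wherever they lie, is argued against by the odds ratio, whose lower 95% bound was 4.74 in eye and higher in brain. A haplotype of 10 Mb around the gene is argued against as the whole source by a lower bound of 3.80 for genes farther away. Both bounds count genes as independent and may be too high. By whole chromosomes, 8.51% of genes were called here in eye, and at most 2.45% on any other. In brain the shares were 8.04% and at most 1.35%. Loss in mapping of reads from wh5 alone would lower genes, so the higher genes fall outside it by definition. Their share (lower bound 39.0% in brain) argues against such loss only as the whole source. It stays open for the lower genes (upper bound of their share 61.0% in brain), as does an untested loss of WT reads for the higher genes. A chromosome inherited with the allele that acts in cis may explain the concentration. The share of called genes with the same sign in the other organ exceeded that elsewhere by amounts whose lower bound was -4.79 percentage points in eye. Any genotype effect that both organs share gives equal signs, so this share cannot single out an effect in cis. Such an effect cannot be told apart from the other open explanations.

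Called genes on the other chromosomes may also lie in blocks that differ between the 2 lines, which is a hypothesis. In eye, 69 of 256 such genes had another called gene among the 5 tested genes on either side, against a median of 34 and a highest count of 63 in 10000 shuffles (permutation p = 0.0001, the smallest that they can give). In brain the count was 12 of 81, against a median of 4 and a highest count of 15 (permutation p = 0.0068). Clusters of related genes that are regulated together would give the same count.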
